A study of Drosophila melanogaster with 20 samples.

How the data were processed

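Total RNA from dissected wing imaginal discs of Drosophila was labelled by in vitro transcription and hybridised to Affymetrix arrays, 1 array per sample, per the labels' protocols. There were 20 arrays in 5 groups of 4, and each group and replicate number was taken from the sample titles. The deposited values are log2 expression levels, 1 per probe set and array, that the authors made with RMA, per the submitters' processing notes, which name RMA and limma without versions. Whether the array that the authors set aside, E_EHT replicate 1, was normalized together with the others is not given in the sources used here, nor are the settings of the background correction and the summarisation. RMA forces the distributions of the arrays to be nearly equal, so a change of most genes in 1 direction would be removed before any comparison, and it compresses differences between dim probe sets.

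The table had 16322 probe sets. The platform annotation gave 1 gene symbol for 13441 of them, several for 555 and none used here for 2326, and only probe sets with 1 symbol were named and tested. For the 37 genes with more than 1 probe set, the probe set with the highest mean over the 19 arrays was used, which left 13402 genes. Gene IDs of 13064 probe sets matched the RefSeq gene table (assembly Release 6 plus ISO1 MT), from which coordinates were taken; these are the positions of genes, not of probes. The labels name no genome build. An array has no read depth, and its precision is limited by the number of arrays: the median standard error of a log2 fold change was 0.093 with 4 arrays in both groups, 0.1 in comparisons with E_EHT and 0.137 for the difference between genotypes. Arrays of 1 group differed by an SD of 0.225 to 0.497 per pair over all genes, and no pair held more than 2 genes with values equal in all deposited digits, so none was counted as a copy.

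The 19 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes without a trend, 14 residual and 2.63 prior degrees of freedom), so that all groups shared 1 estimate of the spread. The 7 comparisons were psqRNAi against none at 12 hr and at day 4, day 4 against 12 hr in each genotype, day 11 against day 4 and against 12 hr with psqRNAi, and the difference between the genotypes in the change from 12 hr to day 4. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 13402 genes of each comparison, with a threshold of 0.05. Every adjusted p of a gene is from limma. Values of a group are given as mean ± SD, log2 fold changes with the standard error of the model, and folds are 2 to the power of the absolute log2 fold change. Comparisons that use the same arrays share their chance values, and the overlap of called genes was counted only for pairs of comparisons that share none.

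Gene lists were fixed before the data were examined, as were the model, the alternatives and the rule for named genes. There were 32 lists, 23 of pathways and 9 of other cell types, sex or transgene markers that dissected discs could hold, and 31 with at least 5 measured members were tested; of the transgene markers only y was measured. Of the 708 entries, 190 have no probe set with that single symbol and are not analysed here, among them Ldh, Mmp1 and upd3. The lists of glycolysis, hypoxia and JNK were written in the knowledge that work of this laboratory on such tumors dealt with lactate dehydrogenase, so they are not blind to the study. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 31 lists, and again with a correlation estimated from the data. Of the 75 list shifts called with the preset correlation, 1 held with the estimated correlation, that of JNK and stress signalling from 12 hr to day 11.

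The rule for named genes was as follows. psq and Egfr came first in every comparison. Up to 8 genes with the largest rise and 8 with the largest fall could be named among those with an adjusted p below 0.05, a log2 fold change of at least 1 in size and no overlap between the arrays of both groups. Up to 4 members of each list with the largest absolute log2 fold change could be named too, and genes named in 1 comparison could be followed in others. Members named without a value, to spell out a small count, and the gene sets of the closing observations were chosen after their values were seen.

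In 5 simulated tests, 200 of 13402 genes were changed. Of 1.5-fold changes, 73.1% were recovered between the genotypes at day 4, 53.7% in the difference between genotypes and 79.4% to 82.1% in other comparisons. Of the calls, 3.9% to 6% were false, a rate that leaves out the structure found among the real arrays. Alternatives were E_EHT replicate 1 kept, a further quantile normalization, arrays centred on their medians, dim genes removed, a trended robust variance, array weights, only the groups compared, other choices of probe set, the replicate number as a block, the estimated correlation and each array left out in turn. A correction for a trend with gene length and expression level was added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.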

Results

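Gene expression was measured on Affymetrix arrays in wing imaginal discs of Drosophila, the larval epithelial sacs from which the adult wing and dorsal thorax form. Each sample held the total RNA of about 20 pairs of discs, and there were 5 groups of 4 arrays that the labels call biological replicates. The discs carried EGFR, the epidermal growth factor receptor, alone or together with psqRNAi, an RNA interference construct against pipsqueak (psq), which encodes a nuclear BTB-domain protein that binds GAGA-type DNA sequences. Discs taken at 12 hr, before tumors had formed, made up E_Ctrl (EGFR) and EP_Ctrl (EGFR with psqRNAi). Hyperplastic tumors of day 4 made up E_EHT and EP_EHT in the same order, and neoplastic tumors of day 11 with EGFR and psqRNAi made up EP_LNT. Replicate 1 of E_EHT, which the submitters set aside for technical problems, was left out, so that 19 arrays entered the comparisons and E_EHT had n = 3. The values were log2 expression levels from RMA, between 2.67 and 14.19 over all probe sets. The medians of the 19 arrays over the 13402 named genes were 7.29 to 7.39. Discs without EGFR and undisturbed discs of the same ages are not analysed here, so each comparison over time covers the age of the discs and the growth of the tumor together.

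The arrays of 1 group were not all alike. EP_LNT replicate 4 lay nearer to the day 4 arrays than the other day 11 arrays did, and its haemocyte marker list averaged 8.4, against 9.5 to 9.55 on the other 3. The dosage compensation transcript lncRNA:roX1, which is made in males, stood at 7.87 on that array and at 12.05 or above on the other 18. The 8 salivary gland markers, mostly glue protein genes, averaged 10.63 to 11.26 on EP_EHT replicates 1 to 3 and 7.51 on replicate 4, and they ranged from 7.85 to 11.64 among the 4 E_Ctrl arrays and from 8.07 to 11.42 among the 4 EP_Ctrl arrays.

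The first comparison asked what psqRNAi changed in EGFR discs at 12 hr, before tumors formed, with n = 4 and 4. psq (chromosome 2R, 10557888 to 10617280, Release 6) stood at 10.78 ± 0.14 (SD) in EP_Ctrl and 10.87 ± 0.05 (SD) in E_Ctrl, and Egfr (2R, 21522420 to 21559977) at 12.57 ± 0.15 and 12.49 ± 0.08. Neither difference passed the test, with log2 fold changes of -0.09 ± 0.09 (SE, adjusted p = 0.675) for psq and 0.08 ± 0.1 (adjusted p = 0.762) for Egfr. Where the psq probe set lies relative to the RNAi target is not known here, so its values do not check the knockdown. The deepest fall was that of Mrp4 (3R, 11569250 to 11575937), an ABC transporter gene, which was 29-fold lower with psqRNAi (log2 fold change -4.86 ± 0.11, adjusted p = 2.4e-14). A cluster of small nucleolar RNAs that guide pseudouridylation of 18S ribosomal RNA rose: snoRNA:Psi18S-525b (2L, 20418670 to 20418804) at least 37.6-fold, snoRNA:Psi18S-640g (2L, 20421781 to 20421909) 12.3-fold and snoRNA:Psi18S-525d 4.21-fold. Their log2 fold changes were 5.23 ± 0.24, 3.62 ± 0.23 and 2.08 ± 0.19, with adjusted p of 9.01e-10, 7.3e-08 and 1.07e-05. The first stood at 3.41 ± 0.26 (SD) in E_Ctrl, near the lowest value of the table, and was not shown to lie above background there, so its folds are lower bounds. These copies are similar in sequence, so cross-hybridisation between them leaves each value uncertain. CG8916 (X, 15921955 to 15924558) rose 12.4-fold (3.63 ± 0.3, adjusted p = 3.13e-06).

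Further genes that rose at 12 hr were CG34278 (7.11-fold), CG43176 (6.82-fold) and CG7906 (4.13-fold), with adjusted p of 0.0445, 0.00543 and 0.0226. The serpin gene Spn47C fell by 1.79 ± 0.21 on the log2 scale (adjusted p = 0.000113), the DEG/ENaC channel gene ppk13 by 1.35 ± 0.18 (4e-04), tut by 1.28 ± 0.13 (3.03e-05) and sordd2 by 1.27 ± 0.26 (adjusted p = 0.0118). GstE1, which encodes a glutathione transferase, fell by 0.91 ± 0.11 (adjusted p = 0.000113). y, the yellow pigmentation gene that some transgenes carry as a marker, rose 1.66-fold (0.73 ± 0.11, adjusted p = 0.00105).

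The cell cycle and DNA replication list shifted down with psqRNAi at 12 hr: of 32 measured members, 0 rose, 2 fell and 30 did not pass, and 16 fell adjusted over the list alone. The list's mean log2 fold change was -0.18 (camera adjusted p = 2.27e-10, adjusted p = 0.943 with an estimated correlation). The 2 were aurB, the Aurora B mitotic kinase (-0.49 ± 0.1, adjusted p = 0.00976), and Mcm3, a subunit of the replicative helicase (-0.4 ± 0.09, adjusted p = 0.0236). Ribosome biogenesis and Myc genes shifted down by a mean of 0.1, with 0 of 17 members past the test over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0288, adjusted p = 0.992 with an estimated correlation). The ecdysone response genes shifted up by a mean of 0.37, with 0 of 20 members past the test and 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.0205, adjusted p = 0.992 with an estimated correlation). Of 32 larval and pupal cuticle genes, 2 rose, 0 fell and 30 did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.992 with an estimated correlation). The 2 were verm and serp, which encode chitin deacetylases.

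In all, 89 genes rose and 236 fell at 12 hr, 15 and 10 of them by at least 2-fold, and 2087 genes had an unadjusted p below 0.05. The other 27 lists tested had camera adjusted p from 0.2 to 0.984. The total of 325 genes was 153 to 214 without E_Ctrl replicates 1, 2 or 4, 512 without E_Ctrl replicate 3, 186 without EP_Ctrl replicate 3, 208 without EP_Ctrl replicate 4, 873 with array weights and 206 with E_EHT replicate 1 kept. The calls of CG34278, CG43176, CG7906 and Mcm3 were lost under at least 1 alternative or left-out array, those of the other 12 named genes under none, and CG34278 had log2 fold changes of 3.47 and 2.15 without EP_Ctrl replicates 1 and 4. The 4 list shifts became 7 without dim genes and 2 without EP_Ctrl replicate 3 or E_Ctrl replicate 1 or 4, and those of ecdysone response, ribosome biogenesis and cuticle were each lost without at least 1 of the 8 arrays. That of ribosome biogenesis was -0.06 without EP_Ctrl replicate 3, and that of cuticle 0.1 without EP_Ctrl replicate 4.

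At day 4, the comparison of EGFR tumors with and without psqRNAi (n = 4 and 3) shared 94 of its 425 genes, in the same direction, with the 325 of 12 hr. psq was 10.7 ± 0.18 (SD) in EP_EHT and 11.15 ± 0.05 in E_EHT, a 1.36-fold fall (log2 fold change -0.45 ± 0.1 SE, adjusted p = 0.0163), and Egfr was 12.66 ± 0.25 and 12.78 ± 0.05 (-0.12 ± 0.11, adjusted p = 0.614). Mrp4 was 25.6-fold lower (-4.68 ± 0.12, adjusted p = 1.58e-13), and snoRNA:Psi18S-525b rose at least 48.9-fold from 3.27 in E_EHT, snoRNA:Psi18S-640g 13.2-fold and CG8916 15.2-fold (adjusted p = 9.01e-10, 9.53e-08 and 2.37e-06). hpRNA:CR32207 (3L, 19477329 to 19478720), a hairpin RNA gene with similar copies beside it, rose 5.21-fold (2.38 ± 0.12, adjusted p = 9.01e-10). The antifungal peptide gene Drs (3L, 3369556 to 3369942) was 17.6-fold lower in EP_EHT (-4.14 ± 0.73, adjusted p = 0.0045). Across the genes that changed, 48 rose at both times where independent lists would share 2.13, 46 fell at both where they would share 1.85, and 0 went opposite ways.

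**Figure D1:**
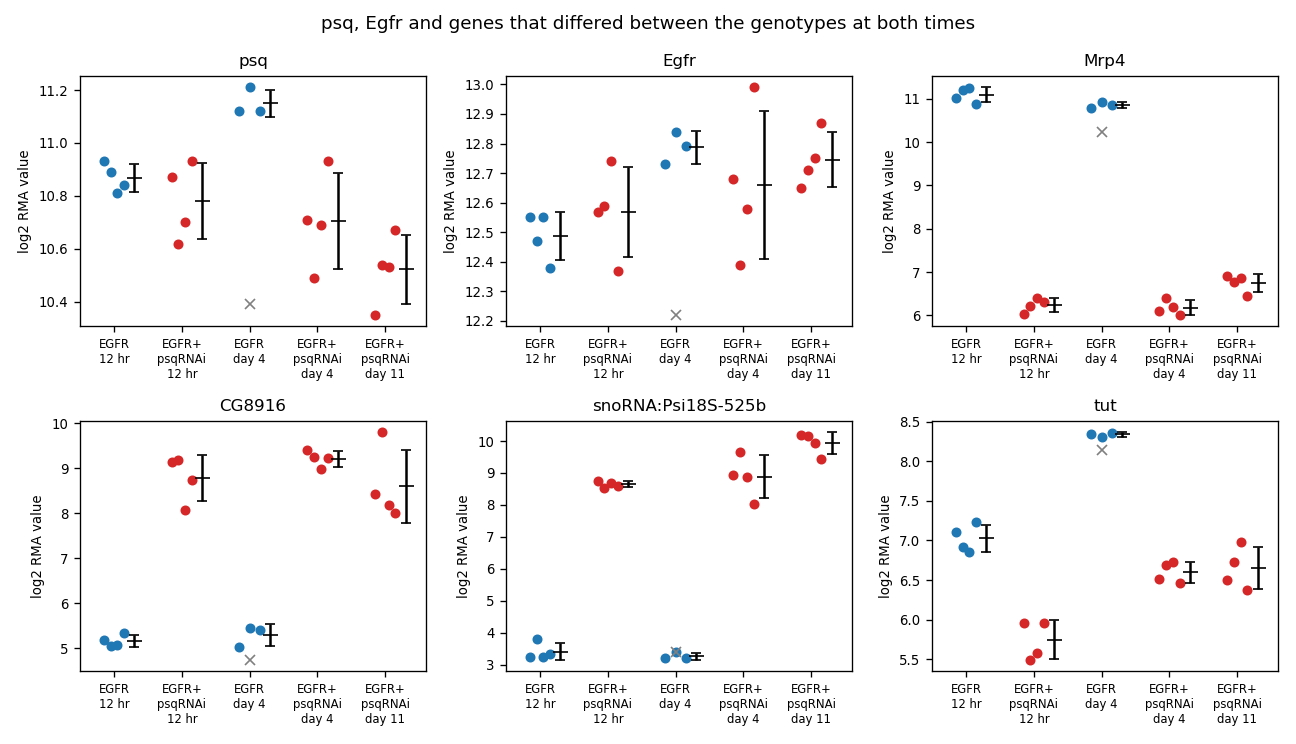
Log2 RMA values (vertical axes) of psq, Egfr, Mrp4, CG8916, snoRNA:Psi18S-525b and tut on each array, by group, with the mean and SD of each group beside the points. The grey cross is E_EHT replicate 1, which was left out. For Mrp4 the EGFR arrays averaged 11.1 at 12 hr and the arrays with psqRNAi 6.24.

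Other genes that rose with psqRNAi at day 4 were CG34278 (8.42-fold), Jhbp7 (5.05-fold), of the juvenile hormone binding protein family, and the heat shock gene Hsp70Bbb (4.69-fold), with adjusted p of 0.0371, 0.0077 and 0.036. CG8160 fell by 3.04 ± 0.7, tut (3L, 8209577 to 8210743) by 1.74 ± 0.14, ppk13 by 1.6 ± 0.19 and dtr by 1.36 ± 0.15 on the log2 scale (adjusted p = 0.0254, 1.76e-06, 0.000117 and 4.61e-05). GstE1 was again lower, by a log2 fold change of -0.56 ± 0.11 (adjusted p = 0.0128), and y higher, by 0.61 ± 0.12 (adjusted p = 0.00763).

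Of 31 oxidative phosphorylation genes, 1 rose with psqRNAi at day 4, 0 fell and 30 did not pass, and 8 rose adjusted over the list alone, with a mean log2 fold change of 0.21 (camera adjusted p = 5.42e-09, adjusted p = 0.677 with an estimated correlation). ATPsynG, an ATP synthase subunit, rose 1.5-fold (0.59 ± 0.12, adjusted p = 0.0141). The TCA cycle list, with 0 of 13 members past the test and 0 adjusted over the list alone, shifted up by 0.13 (camera adjusted p = 0.00332, adjusted p = 0.677 with an estimated correlation). Of 17 ribosome biogenesis and Myc genes, 4 rose, 0 fell and 13 did not pass, and 6 rose adjusted over the list alone (camera adjusted p = 1.57e-05, adjusted p = 0.677 with an estimated correlation). They were Nop56, of the box C/D snoRNA particle (1.32-fold, adjusted p = 0.0307), nclb (1.26-fold, 0.0302), eIF6, a factor for the large ribosomal subunit (1.21-fold, adjusted p = 0.0203), and Tif-IA, an initiation factor of RNA polymerase I. Of 23 ribosomal protein genes, 1 rose, RpS21 (1.29-fold, adjusted p = 0.0397), 0 fell and 22 did not pass, and 4 rose adjusted over the list alone (mean 0.09, camera adjusted p = 0.00149, adjusted p = 0.677 with an estimated correlation). With a trend on gene length and level removed, the mean of this list was 0 (camera adjusted p = 0.941). The heat shock and unfolded protein response list had 0 of 15 members past the test and 0 adjusted over the list alone, with a mean of 0.19 (camera adjusted p = 0.0492, adjusted p = 0.677 with an estimated correlation).

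The antimicrobial immunity list shifted down with psqRNAi at day 4: of 19 members, 0 rose, 2 fell and 17 did not pass, and 4 fell adjusted over the list alone (mean log2 fold change -0.61, camera adjusted p = 0.00189, adjusted p = 0.677 with an estimated correlation). On E_EHT replicate 2 the list stood at 8.52, against 7.65 and 7.72 on replicates 3 and 4, and without it the shift was -0.33 (camera adjusted p = 0.0793). The 2 that fell were Drs and Dif, a Toll pathway transcription factor. Cell polarity and junction genes shifted down by 0.13, with 0 rises, 1 fall (sinu, a claudin) and 23 not past the test among 24, and 4 falls adjusted over the list alone (camera adjusted p = 0.000119, adjusted p = 0.677 with an estimated correlation). The chromatin and Polycomb list shifted down by 0.13, with psq itself the only 1 of 16 that fell and 0 that rose, and with 1 rise and 4 falls adjusted over the list alone (camera adjusted p = 0.00299, adjusted p = 0.677 with an estimated correlation). The wing disc patterning list shifted down by a mean of 0.14, with 1 rise, 0 falls and 33 not past the test among 34, and 1 rise and 1 fall adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.798 with an estimated correlation). Its rise was that of ac, a proneural gene (1.56-fold, 0.64 ± 0.13, adjusted p = 0.00996). Of 9 Hippo targets, 0 passed and 1 fell adjusted over the list alone (camera adjusted p = 0.0187, adjusted p = 0.677 with an estimated correlation). Of 12 neuron and glia markers, 1 fell, 0 rose and 11 did not pass, and 1 fell adjusted over the list alone (camera adjusted p = 0.0379, adjusted p = 0.677 with an estimated correlation). This was elav, a neuronal RNA-binding protein gene (-0.35 ± 0.09, adjusted p = 0.0432).

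At day 4, 320 genes were higher and 105 lower with psqRNAi, 30 and 11 by at least 2-fold, 2319 genes had an unadjusted p below 0.05, and 20 lists were not called (camera adjusted p from 0.143 to 0.978). The total of 425 genes was 64 with only the 2 groups in the model, 645 without dim genes, and 804 with array weights. It was 1134 without EP_EHT replicate 4, 191 and 256 without EP_EHT replicates 1 and 2, and 231, 183 and 179 without E_EHT replicates 2, 3 and 4. The call of psq ended without E_EHT replicate 3 or 4, with replicate 1 kept and with only the 2 groups, and its adjusted p ranged from 0.00241 to 0.375 over all settings. Of the 23 named calls, 9 held under every alternative and left-out array: those of both snoRNAs, CG8916, hpRNA:CR32207, Mrp4, Drs, tut, ppk13 and dtr. Without E_EHT replicate 3, Drs and CG8160 had log2 fold changes of -4.77 and -3.79. The shifts of Hippo targets, wing disc patterning, antimicrobial immunity, heat shock and neurons were each lost without at least 1 of the 7 arrays. With E_EHT replicate 1 kept, those of the TCA cycle, cell polarity and chromatin were lost too and 4 lists were called in place of 11, and 7 were with the length and level trend removed. Without EP_EHT replicate 2 the shift of wing disc patterning was -0.02, that of Hippo targets -0.09 and those of cell polarity and chromatin both -0.08. Without EP_EHT replicate 4 wing disc patterning and Hippo targets both had -0.24, and without EP_EHT replicate 1 the heat shock list had 0.12.

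Day 4 EGFR tumors were set against 12 hr EGFR discs to show what changed as hyperplastic tumors formed (n = 3 and 4). psq had a log2 fold change of 0.28 ± 0.1 (SE, adjusted p = 0.0845) and Egfr of 0.3 ± 0.11 (adjusted p = 0.117). Ilp8 (3L, 17029812 to 17032080), a relaxin-like peptide gene whose product delays pupariation, rose 11.3-fold, from 7.76 ± 0.21 (SD) to 11.26 ± 0.26 (3.5 ± 0.28, adjusted p = 5.62e-06). krimp (2R, 16238103 to 16240722), which encodes a Tudor-domain protein of the piRNA pathway, rose 4.96-fold (2.31 ± 0.12, adjusted p = 1.52e-08), and AGO3, an Argonaute of that pathway, rose 1.76-fold (adjusted p = 8.28e-05). Of immune genes, Drs rose 11.2-fold and the Toll-induced peptide genes BomS6 and BomT2 10.5-fold and 4.4-fold (adjusted p = 0.0112, 0.00877 and 0.00778). The heat shock gene Hsp70Bbb fell 4.13-fold (adjusted p = 0.0366) and CG12926 2.31-fold (adjusted p = 0.00694).

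Of 20 genes of JNK and stress signalling, 6 rose, 0 fell and 14 did not pass in EGFR tumors at day 4, and 11 rose and 1 fell adjusted over the list alone (mean log2 fold change 0.53, camera adjusted p = 8.74e-06, adjusted p = 0.111 with an estimated correlation). With Ilp8 rose the transcription factor genes Ets21C (2.41-fold), ftz-f1 (2.17-fold) and Atf3 (1.84-fold), with adjusted p of 0.00314, 0.00272 and 0.0234, and egr, the TNF ligand gene (1.84-fold, adjusted p = 0.0206). Of 9 JAK/STAT genes, 1 rose, 0 fell and 8 did not pass, and 4 rose adjusted over the list alone (camera adjusted p = 0.000545, adjusted p = 0.149 with an estimated correlation). This was chinmo (2L, 1651258 to 1704682), a BTB-domain transcription factor gene, which rose 2.95-fold (1.56 ± 0.23, adjusted p = 0.00137). Of 20 extracellular matrix and adhesion genes, 4 rose, 0 fell and 16 did not pass, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00141, adjusted p = 0.45 with an estimated correlation). Ndg, the basement membrane protein nidogen, rose 1.99-fold (adjusted p = 0.00637), and so did the laminin genes LanA and LanB1 and the talin gene rhea. Of 19 antimicrobial immunity genes, 4 rose, 0 fell and 15 did not pass, and 4 rose adjusted over the list alone (mean 0.48, camera adjusted p = 0.00129, adjusted p = 0.45 with an estimated correlation). Without E_EHT replicate 2, on which this list stood at 8.52 against 7.65 and 7.72, the mean was 0.2 (camera adjusted p = 0.153). Besides Drs, those that rose included the transcription factor Dif (1.59-fold, adjusted p = 0.00416), and outside this list the serine protease homolog SPH93 rose 3.81-fold (adjusted p = 0.0378) and CG8160 rose 8.89-fold (adjusted p = 0.0155).

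Of 31 oxidative phosphorylation genes, 0 rose, 6 fell in EGFR tumors by day 4 and 25 did not pass, and 22 fell adjusted over the list alone (mean log2 fold change -0.25, camera adjusted p = 7e-12, adjusted p = 0.393 with an estimated correlation). ATPsynG fell by 0.51 ± 0.12, COX8, of cytochrome c oxidase, by 0.47 ± 0.1 and ATPsyngamma by 0.4 ± 0.08 on the log2 scale (adjusted p = 0.0227, 0.0126 and 0.00749). Of 12 genes of glycolysis and lactate, 0 rose, 3 fell and 9 did not pass, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.483 with an estimated correlation). The 3 were Gapdh1 (-0.49 ± 0.1, adjusted p = 0.00852), Pglym78 (-0.42 ± 0.12, adjusted p = 0.0492) and Pgk. Of 13 TCA cycle genes, 0 passed and 6 fell adjusted over the list alone (camera adjusted p = 0.00656, adjusted p = 0.483 with an estimated correlation). Of 17 ribosome biogenesis and Myc genes, 1 rose, 7 fell and 9 did not pass, and 1 rose and 14 fell adjusted over the list alone (camera adjusted p = 8.07e-07, adjusted p = 0.393 with an estimated correlation). Nop56 fell 1.29-fold (adjusted p = 0.0347), while Non1, a nucleolar GTPase gene, rose 1.37-fold (adjusted p = 0.00212). Of 15 heat shock and unfolded protein response genes, 0 rose, 3 fell and 12 did not pass, and 4 fell adjusted over the list alone (camera adjusted p = 0.000545, adjusted p = 0.41 with an estimated correlation). Hsp26 fell 1.7-fold, Hsc70-3, the BiP chaperone of the endoplasmic reticulum, fell 1.51-fold (adjusted p = 0.0155 and 0.00314), and Gp93 also fell.

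Of 28 redox and detoxification genes, 3 fell by day 4 with EGFR, among them GstO3 (1.41-fold, adjusted p = 0.00428), 0 rose and 25 did not pass, and 3 fell adjusted over the list alone (camera adjusted p = 0.0357, adjusted p = 0.558 with an estimated correlation). The ribosomal protein list had 0 of 23 members past the test, also adjusted over the list alone, and a mean of -0.06 (camera adjusted p = 0.0472, adjusted p = 0.719 with an estimated correlation). With a trend on gene length and level removed, its direction turned (mean 0.05, camera adjusted p = 0.0168). Of 32 cuticle genes, 3 rose (Cht7, verm and serp), 0 fell and 29 did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.558 with an estimated correlation). Of 9 Hippo targets, 1 rose, kibra (1.35-fold, adjusted p = 0.0186), 0 fell and 8 did not pass, and 1 rose adjusted over the list alone (camera adjusted p = 0.0479, adjusted p = 0.558 with an estimated correlation). Of 12 neuron and glia markers, 1 rose, moody, a glial receptor gene (1.53-fold, adjusted p = 0.035), 0 fell and 11 did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.0229, adjusted p = 0.558 with an estimated correlation). fru, a sex-determination gene, rose 1.83-fold (adjusted p = 0.00341), and wbl fell 2.76-fold (adjusted p = 0.0394).

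In EGFR tumors 264 genes rose and 618 fell by day 4, 25 and 9 by at least 2-fold, 3070 genes had an unadjusted p below 0.05, and 17 lists were not called (camera adjusted p from 0.0737 to 0.984). Risen genes made up 29.9% of those changed, 40.9% after a further quantile normalization and 17.4% with each array centred on its median. The total of 882 genes was 2238 with array weights. It was 524, 474 and 375 without E_Ctrl replicates 1, 2 and 4 and 345, 273 and 331 without E_EHT replicates 2, 3 and 4. Of the 31 named calls, 14, those of Ilp8, krimp, chinmo and Ets21C among them, held under every alternative and left-out array. Those of Drs, BomS6, CG8160, SPH93, Hsp70Bbb, wbl, Atf3, egr, Pglym78, ATPsynG, COX8, Hsp26, Nop56, moody and kibra were each lost without at least 1 of the 7 arrays. CG12926 was lost with E_EHT replicate 1 kept and fru with the length and level trend removed. Without E_EHT replicate 3 the log2 fold changes of Drs and CG8160 were 4.11 and 3.91, and without E_EHT replicate 2 that of BomS6 was 2.78. The shifts of Hippo targets, ribosomal proteins, antimicrobial immunity, redox, cuticle and neurons were each lost without at least 1 array, and those of glycolysis, the TCA cycle and extracellular matrix under at least 1 other alternative. With E_EHT replicate 1 kept 7 lists were called in place of 14.

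With EGFR and psqRNAi, day 4 tumors were set against 12 hr discs in the same way (n = 4 and 4). psq had a log2 fold change of -0.07 ± 0.09 (SE, adjusted p = 0.755) and Egfr of 0.09 ± 0.1 (adjusted p = 0.736). Ilp8 rose 8.06-fold (3.01 ± 0.26, adjusted p = 5.65e-06), krimp 4.2-fold (2.07 ± 0.11, adjusted p = 2.59e-08), AGO3 1.65-fold (adjusted p = 9.83e-05) and Jhbp7 (3R, 25237614 to 25238895) 6.74-fold (2.75 ± 0.41, adjusted p = 0.00115). The cytochrome P450 gene Cyp4e3 rose 8.82-fold and BomS6 5.51-fold (adjusted p = 0.0428 and 0.0321), with wide errors of 0.85 and 0.63. The serpin gene Spn100A fell 5.42-fold (adjusted p = 0.00654), and CG7906 4.81-fold (adjusted p = 0.00847). TwdlE, a cuticle protein gene, fell 4.08-fold (adjusted p = 0.00933) and lncRNA:let7C, the host transcript of the let-7 microRNA cluster, 4.18-fold (adjusted p = 0.0101). Of the genes that rose, 111 also rose with EGFR alone, where independent lists would share 7.78; 67 fell in both, where they would share 11, and 1 went opposite ways.

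Of 20 JNK and stress signalling genes, 8 rose, 0 fell and 12 did not pass by day 4 with EGFR and psqRNAi, and 9 rose adjusted over the list alone (mean log2 fold change 0.56, camera adjusted p = 2.27e-06, adjusted p = 0.0584 with an estimated correlation). They included Ets21C (2.86-fold), ftz-f1 (2.52-fold), mol, a Duox maturation factor gene (2.43-fold), and egr (2.17-fold), with adjusted p of 0.00032, 0.000232, 0.000383 and 0.0033. Of 9 JAK/STAT genes, 3 rose, 0 fell and 6 did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.0202, adjusted p = 0.6 with an estimated correlation). They were chinmo (3.45-fold, adjusted p = 0.000132) and the ligand genes upd2 (1.74-fold, adjusted p = 0.0235) and upd1 (1.59-fold, adjusted p = 0.0483), and both ligands are also on the JNK list. Of 20 extracellular matrix and adhesion genes, 2 rose, 0 fell and 18 did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.0311, adjusted p = 0.732 with an estimated correlation). Tig, an integrin ligand, rose 2.89-fold and Ndg 1.71-fold (adjusted p = 0.0049 and 0.0167). Of 32 cell cycle and DNA replication genes, 2 rose, 0 fell and 30 did not pass, and 9 rose adjusted over the list alone (camera adjusted p = 5.29e-06, adjusted p = 0.6 with an estimated correlation). Mcm2, a helicase subunit, rose 1.23-fold (adjusted p = 0.0295), and the other was Klp61F, a spindle motor. The ribosomal protein list had 0 of 23 members past the test, also adjusted over the list alone, and a mean of 0.07 (camera adjusted p = 0.00328, adjusted p = 0.732 with an estimated correlation).

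Of 20 ecdysone response genes, 1 rose (ftz-f1), 5 fell and 14 did not pass by day 4 with EGFR and psqRNAi, and 2 rose and 9 fell adjusted over the list alone (mean log2 fold change -0.67, camera adjusted p = 2.24e-05, adjusted p = 0.6 with an estimated correlation). The nuclear receptor gene Hr4 fell 4.39-fold, Blimp-1, an ecdysone-induced repressor gene, 4.32-fold and Hr3 3.7-fold (adjusted p = 0.0213, 0.0138 and 0.0227), and Sb and Hr39 also fell. Salivary gland markers on EP_EHT replicates 1 to 3 and replicate 4 stood at 10.63 to 11.26 and at 7.51. Of 34 wing disc patterning genes, 0 rose, 4 fell and 30 did not pass, and 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 2.24e-05, adjusted p = 0.732 with an estimated correlation). Doc1, a T-box gene, fell 1.72-fold (adjusted p = 0.023), with its neighbours Doc2 and Doc3 and with ara. Of 15 heat shock and unfolded protein response genes, 0 rose, 4 fell and 11 did not pass, and 6 fell adjusted over the list alone (camera adjusted p = 0.000442, adjusted p = 0.6 with an estimated correlation). Hsc70-3 fell 1.43-fold (adjusted p = 0.00433), and the endoplasmic reticulum genes Gp93, Pdi and sip3 fell too. Of 12 glycolysis and lactate genes, 0 rose, 2 fell and 10 did not pass, and 4 fell adjusted over the list alone (camera adjusted p = 0.0047, adjusted p = 0.6 with an estimated correlation). They were Glut1, a glucose transporter (1.85-fold, adjusted p = 0.0435), and Pfk, phosphofructokinase. Of 24 cell polarity and junction genes, 1 rose (nrv2), 0 fell and 23 did not pass, and 1 rose and 1 fell adjusted over the list alone, with a list mean of -0.07 (camera adjusted p = 0.0237, adjusted p = 0.83 with an estimated correlation). Elsewhere, GstE1 rose 1.62-fold (adjusted p = 0.00119), fru 1.88-fold (adjusted p = 0.00116) and Dark, the Apaf-1 homolog, fell 1.28-fold (adjusted p = 0.0352).

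With EGFR and psqRNAi 395 genes rose and 238 fell by day 4, 52 and 43 by at least 2-fold, 2341 genes had an unadjusted p below 0.05, and 21 lists were not called (camera adjusted p from 0.117 to 0.947). The total of 633 genes was 267 with only the 2 groups in the model, 388 and 412 without EP_Ctrl replicates 1 and 4, and 307 without EP_EHT replicate 2. The calls of Cyp4e3, BomS6, Hr4, Hr3, upd1, upd2, Ndg, Mcm2, Doc1, Glut1 and Dark were each lost without at least 1 of the 8 arrays, that of lncRNA:let7C with only the 2 groups, and the other 17 of the 29 named calls under no alternative or left-out array. Without EP_EHT replicate 1 the log2 fold change of Cyp4e3 was 3.83. The shifts of glycolysis, JAK/STAT, extracellular matrix, cell polarity and ribosomal proteins were each lost without at least 1 array. Without EP_EHT replicate 2 those of ecdysone response, wing disc patterning, cell polarity and ribosomal proteins were -0.44, -0.1, -0.02 and 0.04. The shift of cell polarity was -0.13 without EP_EHT replicate 4, and that of glycolysis -0.13 without EP_Ctrl replicate 4.

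Day 11 neoplastic tumors were next set against day 4 hyperplastic tumors with EGFR and psqRNAi (n = 4 and 4). psq had a log2 fold change of -0.18 ± 0.09 (SE, adjusted p = 0.265) and Egfr of 0.09 ± 0.1 (adjusted p = 0.727). Spn47C (2R, 10938425 to 10941738) rose 5.05-fold (2.34 ± 0.21, adjusted p = 8.55e-06), CG12481 5.39-fold (2.43 ± 0.23, adjusted p = 1.21e-05), Drs 6.04-fold (2.59 ± 0.67, adjusted p = 0.0262, and 1.73 without EP_LNT replicate 1, on which it stood at 10.36 against 6.24 to 7.56) and nrv3, a sodium pump subunit gene, 4.28-fold (2.1 ± 0.51, adjusted p = 0.0181). CG8664 (X, 17280918 to 17282726) fell 14.8-fold (adjusted p = 0.00288), the protease gene yip7 8.91-fold (adjusted p = 0.0203) and the lysozyme gene LysS 7.16-fold (adjusted p = 0.0334). Cuticle genes Vajk2 and Cpr49Ag fell 5.1-fold and 4.62-fold (adjusted p = 0.00503 and 5.7e-06), and the fat body genes Fbp2 (2L, 9426784 to 9427917) and Lsp2 4.95-fold and 2.68-fold (adjusted p = 2.59e-05 and 0.000295).

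Of 12 Notch pathway genes, 7 rose, 0 fell and 5 did not pass between day 4 and day 11, and 9 rose and 1 fell adjusted over the list alone (mean log2 fold change 0.39, camera adjusted p = 1.14e-06, adjusted p = 0.252 with an estimated correlation). All 7 lie in the Enhancer of split complex of Notch targets, and E(spl)m3-HLH rose 1.73-fold and E(spl)m7-HLH 1.72-fold (adjusted p = 0.000364 and 0.00141). Of 13 EGFR pathway genes, 5 rose, 0 fell and 8 did not pass, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.476 with an estimated correlation). They were the feedback inhibitors sty (1.6-fold) and aos (1.55-fold), edl (1.48-fold), Mkp3 and the ligand gene spi, with adjusted p of 0.00402, 0.00141 and 0.000663 for the first 3. Of 20 JNK and stress signalling genes, 5 rose, 1 fell and 14 did not pass, and 9 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000279, adjusted p = 0.252 with an estimated correlation). Pvf1, a PDGF/VEGF-like ligand gene, rose 2.16-fold (adjusted p = 2.35e-05) and mol 1.75-fold (adjusted p = 0.00719), with puc, msn and grnd. The ligand gene upd1 fell 1.59-fold (adjusted p = 0.0366). Of 20 extracellular matrix and adhesion genes, 4 rose, 0 fell and 16 did not pass, and 5 rose adjusted over the list alone (camera adjusted p = 0.000474, adjusted p = 0.429 with an estimated correlation). They were the metalloproteinase gene Mmp2 (1.82-fold, adjusted p = 0.00387), its inhibitor gene Timp (1.84-fold, adjusted p = 0.011), rhea and the integrin gene mys. On EP_LNT replicate 4 this list stood at 9.04, within the day 4 range of 8.94 to 9.18, against 9.3 to 9.48 on the other 3, and the haemocyte list was low there too (8.4). Of 12 growth signalling and insulin genes, 2 rose, 0 fell and 10 did not pass, and 4 rose adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.476 with an estimated correlation). They were S6k and ImpL2, a secreted insulin antagonist (1.49-fold, adjusted p = 0.00345).

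Of 14 haemocyte genes, which mark blood cells, 5 rose, 0 fell and 9 did not pass from day 4 to day 11, and 10 rose adjusted over the list alone (mean log2 fold change 0.82, camera adjusted p = 1.75e-07, adjusted p = 0.394 with an estimated correlation). NimC1, a phagocytosis receptor gene, rose 3.38-fold and the scavenger receptor gene Sr-CI 2.45-fold (adjusted p = 0.000977 and 0.0192), and so did He, lz and crq. On EP_LNT replicate 4 the list stood at 8.4 against 9.5 to 9.55 on the other 3 arrays. Beside them, of 19 antimicrobial immunity genes, 5 rose (Drs, spz, Dif, PGRP-LB and Tl), 0 fell and 14 did not pass, and 5 rose adjusted over the list alone (camera adjusted p = 6.83e-05, adjusted p = 0.394 with an estimated correlation). Of 12 neuron and glia markers, 3 rose (nrv3, Snap25 and moody, 2.07-fold, adjusted p = 0.000622), 0 fell and 9 did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.476 with an estimated correlation). Of 8 salivary gland markers, 1 fell, the glue gene Sgs8 (18.5-fold, -4.21 ± 1.09, adjusted p = 0.0261), 0 rose and 7 did not pass, and 5 fell adjusted over the list alone (camera adjusted p = 0.000876, adjusted p = 0.476 with an estimated correlation). Of 9 tracheal markers, 3 fell, 0 rose and 6 did not pass, and 3 fell adjusted over the list alone (camera adjusted p = 0.00204, adjusted p = 0.429 with an estimated correlation). The 3 were kni (1.61-fold, adjusted p = 0.00127) and knrl, which also pattern wing veins, and dysf.

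Of 31 oxidative phosphorylation genes, 0 rose, 3 fell and 28 did not pass between day 4 and day 11, and 6 fell adjusted over the list alone (mean log2 fold change -0.15, camera adjusted p = 1.16e-06, adjusted p = 0.476 with an estimated correlation). sesB, the mitochondrial ADP/ATP carrier, fell 1.2-fold (adjusted p = 0.0205), with blw and COX8. Of 32 cell cycle and DNA replication genes, 2 fell, 0 rose and 30 did not pass, and 2 fell adjusted over the list alone (camera adjusted p = 0.000781, adjusted p = 0.476 with an estimated correlation). These were Mcm3 (1.24-fold, adjusted p = 0.0451) and Cdk2. Of 17 ribosome biogenesis and Myc genes, 1 rose (Non1), 1 fell (Nop60B) and 15 did not pass, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.00822, adjusted p = 0.542 with an estimated correlation). Named members of lists that did not shift were the homeotic gene Scr, which rose 2.7-fold (adjusted p = 0.000137), Eip93F, a temporal regulator induced by ecdysone (2.25-fold, adjusted p = 0.000695), and Hex-A, hexokinase (1.43-fold, adjusted p = 0.000649). zfh2 and bi, transcription factor genes of the wing field, both fell 2.02-fold (adjusted p = 0.00192 and 0.0159), and the morphogen gene hh fell 1.89-fold (adjusted p = 0.00423).

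Between day 4 and day 11, 602 genes rose and 335 fell, 85 and 31 by at least 2-fold, 2715 genes had an unadjusted p below 0.05, and 18 lists were not called (camera adjusted p from 0.142 to 0.848). The total of 937 genes was 1510 without EP_LNT replicate 4, 560 and 539 without EP_LNT replicates 2 and 3, 252 with only the 2 groups in the model, 605 with E_EHT replicate 1 kept and 1773 with array weights. Of the 35 named calls, 18 held under every alternative and left-out array. Those of Drs, nrv3, yip7, LysS, Sr-CI, Sgs8, upd1, bi, sesB and Mcm3 were each lost without at least 1 of the 8 arrays, and those of Timp, sty, E(spl)m7-HLH, zfh2, hh, kni and ImpL2 with only the 2 groups in the model. Without EP_LNT replicates 2 and 4 yip7 had log2 fold changes of -2.28 and -3.87, and without EP_EHT replicates 1 and 2 LysS had -3.54 and -2.15. Sgs8 had -5.26 without EP_EHT replicate 4, where the salivary gland list had -3.68, and -3.53 without EP_LNT replicate 1. The shifts of ribosome biogenesis, growth signalling and neurons were each lost without at least 1 array. Without EP_EHT replicate 2 those of oxidative phosphorylation, EGFR pathway and growth signalling were -0.09, 0.16 and 0.11.

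Day 11 tumors set against 12 hr discs of the same genotype gave the most changes (n = 4 and 4). psq was 10.52 ± 0.13 (SD) against 10.78 ± 0.14, a 1.19-fold fall (log2 fold change -0.26 ± 0.09 SE, adjusted p = 0.0474), and Egfr had 0.18 ± 0.1 (adjusted p = 0.251). Jhbp7 rose 17.4-fold (4.12 ± 0.41, adjusted p = 2.72e-06), Spn47C 13.6-fold (3.76 ± 0.21, adjusted p = 6.64e-09) and CG11400 (2R, 17134129 to 17135345) 10.6-fold (3.41 ± 0.17, adjusted p = 2.02e-09). BomS6 rose 11.5-fold (3.52 ± 0.63, adjusted p = 0.00057) and Ilp8 8.9-fold (3.15 ± 0.26, adjusted p = 3.78e-07). The glue gene Sgs8 fell 21.2-fold and the ecdysone-induced genes Eig71Ee and ImpE2 17.7-fold and 11.6-fold (adjusted p = 0.00715, 0.0318 and 0.00453). yip7 and LysS fell 11.4-fold and 10.9-fold (adjusted p = 0.00326 and 0.00348).

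**Figure D2:**
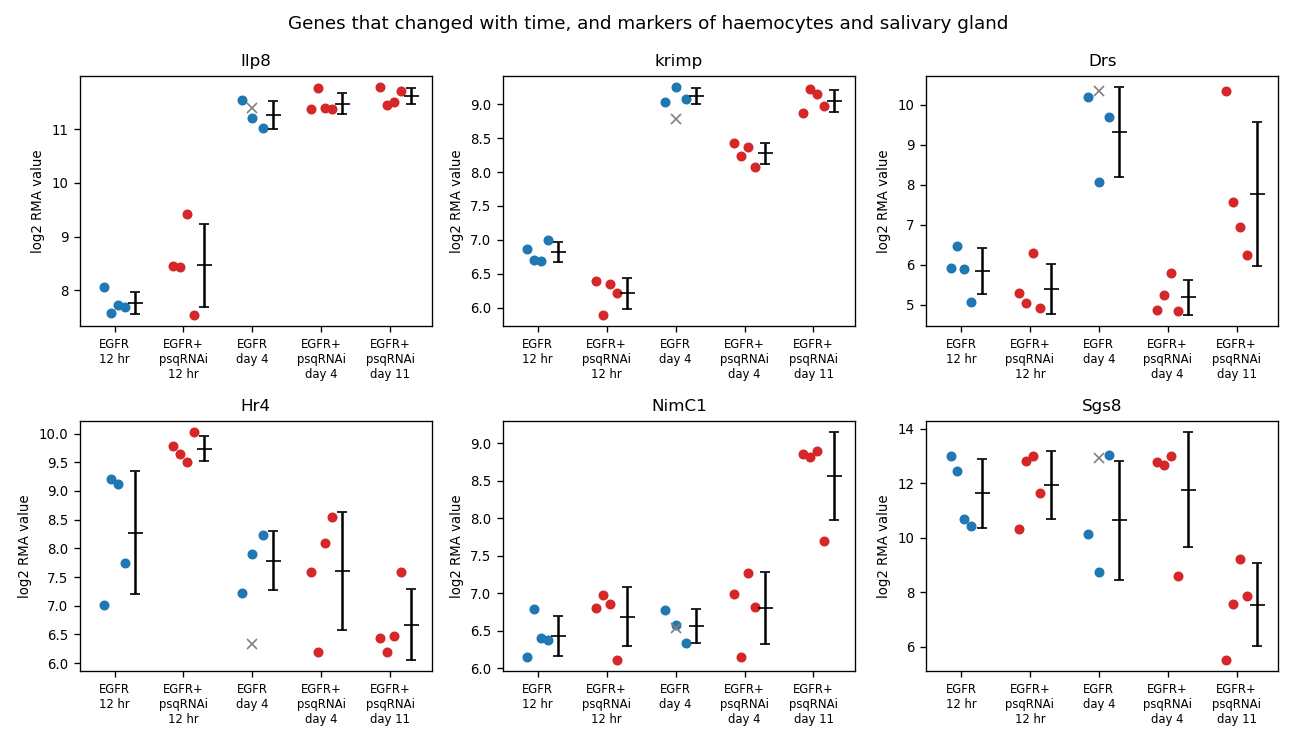
Log2 RMA values (vertical axes) of Ilp8, krimp, Drs, Hr4, NimC1 and Sgs8 on each array, by group, with the mean and SD of each group beside the points and E_EHT replicate 1, which was left out, as a grey cross. The Ilp8 means were 7.76 and 8.46 at 12 hr and between 11.26 and 11.62 at day 4 and day 11.

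Of 20 JNK and stress signalling genes, 15 rose, 1 fell (bsk, the JNK kinase) and 4 did not pass by day 11, with the same counts adjusted over the list alone (mean log2 fold change 0.8, camera adjusted p = 8.72e-08, adjusted p = 0.0268 with an estimated correlation). mol rose 4.25-fold, Ets21C 3.66-fold, ftz-f1 3.34-fold and egr 3.02-fold (adjusted p = 2.8e-07, 4.25e-06, 1.92e-06 and 1.73e-05). Of 20 extracellular matrix and adhesion genes, 12 rose, 0 fell and 8 did not pass, and 13 rose adjusted over the list alone (camera adjusted p = 0.000103, adjusted p = 0.639 with an estimated correlation). Tig rose 3.53-fold and SPARC, a basement membrane protein gene, 2.53-fold (adjusted p = 0.000171 and 0.0021). Of 14 haemocyte genes, 8 rose, 0 fell and 6 did not pass, and 11 rose adjusted over the list alone (camera adjusted p = 0.000103, adjusted p = 0.639 with an estimated correlation). Sr-CI rose 4.1-fold and NimC1 3.67-fold (adjusted p = 0.000176 and 0.000104), and the matrix gene Pxn is on both lists, which stood at 9.04 and 8.4 on EP_LNT replicate 4. Of 12 Notch pathway genes, 6 rose, 0 fell and 6 did not pass, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000916, adjusted p = 0.639 with an estimated correlation). Of these, E(spl)m3-HLH rose 2.46-fold (adjusted p = 3.61e-07). Of 13 EGFR pathway genes, 5 rose, 1 fell (Sos) and 7 did not pass, and 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.71 with an estimated correlation). Here sty rose 1.95-fold and edl 1.68-fold (adjusted p = 5.54e-05 and 7.59e-06). Of 19 antimicrobial immunity genes, 6 rose, 0 fell and 13 did not pass, also adjusted over the list alone (camera adjusted p = 0.00587, adjusted p = 0.682 with an estimated correlation). Dif rose 2.28-fold (adjusted p = 1.13e-06). Of 23 ribosomal protein genes, 5 rose, 0 fell and 18 did not pass, and 8 rose adjusted over the list alone (camera adjusted p = 0.00587, adjusted p = 0.71 with an estimated correlation).

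Of 34 wing disc patterning genes, 6 rose, 17 fell and 11 did not pass by day 11, and 7 rose and 17 fell adjusted over the list alone (mean log2 fold change -0.37, camera adjusted p = 0.000916, adjusted p = 0.71 with an estimated correlation). nub and dve, transcription factor genes of the wing pouch, fell 2.98-fold and 2.87-fold and hh fell 2.48-fold (adjusted p = 0.000851, 0.000224 and 5.69e-05). On EP_LNT replicate 4 this list stood at 9.63, near the 9.65 to 9.84 of 12 hr, against 9.17 to 9.34 on the other 3, and nub at 10.3 against 8.46 to 8.8. Of 20 ecdysone response genes, 5 rose, 11 fell and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.0309, adjusted p = 0.71 with an estimated correlation). Hr4 fell 8.37-fold, Blimp-1 7.57-fold and Hr3 4.92-fold (adjusted p = 0.000272, 0.000195 and 0.00122), and the 5 that rose were ftz-f1, Eip93F, ImpL1, ImpL2 and the receptor gene EcR. This list stood at 9.13 on EP_LNT replicate 4 and at 8.43 to 8.5 on the other 3. Beside them, of 8 salivary gland markers 3 fell (Sgs8, Sgs7 and Eig71Ee), 0 rose and 5 did not pass, and 5 fell adjusted over the list alone (camera adjusted p = 0.00997, adjusted p = 0.71 with an estimated correlation). Of 9 tracheal markers, 1 rose (apt), 6 fell and 2 did not pass, also adjusted over the list alone (camera adjusted p = 0.00437, adjusted p = 0.639 with an estimated correlation). The fall of kni was 1.87-fold (adjusted p = 2.16e-05). Of 31 oxidative phosphorylation genes, 0 rose, 4 fell and 27 did not pass, and 3 fell adjusted over the list alone (camera adjusted p = 0.00082, adjusted p = 0.71 with an estimated correlation). The carrier gene sesB was 1.39-fold lower (adjusted p = 6.33e-05). Of 15 heat shock and unfolded protein response genes, 2 rose, 5 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.0132, adjusted p = 0.687 with an estimated correlation). Hsp27 was 2.02-fold lower (adjusted p = 0.000149).

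The next 6 lists fixed for the tissue were called in no comparison, with these counts by day 11. Of 8 hypoxia response genes, 2 rose, 2 fell and 4 did not pass, and 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.708). Hph, a prolyl hydroxylase gene, rose 1.63-fold and Glut1 fell 2.1-fold (adjusted p = 0.00104 and 0.00375). Of 12 apoptosis genes, 4 rose, 3 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.594), with egr among the first and Dark, 1.42-fold lower (adjusted p = 0.000678), among the second. Of 16 myoblast and muscle markers, 5 rose, 5 fell and 6 did not pass, and 6 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.548), where the median of 0.27 and the upward test differ in sign from the mean of -0.32. Without EP_Ctrl replicate 4, on which this list stood at 8.97 against 7.7 to 8.18, the mean was -0.05 and the median 0.45. Mlc1, a myosin light chain gene, fell 7.3-fold (adjusted p = 0.00231), and 4.86-fold without that array. Of 13 fat body markers, 3 rose, 5 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.126), with Fbp2 5.55-fold and Lsp2 3.04-fold lower (adjusted p = 1.7e-06 and 1.12e-05). Of 7 germline genes, 2 rose, AGO3 (2.34-fold, adjusted p = 3.75e-08) and piwi (1.57-fold, adjusted p = 0.00019), 0 fell and 5 did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.227). Of 7 sex and dosage genes, 2 rose (fru, 2.03-fold, adjusted p = 5.06e-05, and tra), 1 fell (dsx, 1.59-fold, adjusted p = 0.00129) and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.677).

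By day 11, 1618 genes had risen and 1345 fallen, 249 and 193 by at least 2-fold, 4417 genes had an unadjusted p below 0.05, and 18 lists were not called (camera adjusted p from 0.0684 to 0.708). Of the 44 named calls, 42 held under every alternative and left-out array, and those of psq and Eig71Ee did not. Without EP_LNT replicate 4 the log2 fold changes of BomS6, ImpE2 and yip7 were 4.19, -4.32 and -4.23, and without replicate 2 that of yip7 was -2.64. Sgs8 had -3.73 without EP_LNT replicate 1, and Eig71Ee and the salivary gland list -4.86 and -3.51 without EP_Ctrl replicate 1. The shifts of EGFR pathway, ecdysone response and heat shock were each lost without at least 1 of the 8 arrays, and that of the salivary gland list without dim genes. chinmo rose 4.05-fold and Scr 2.84-fold (adjusted p = 3.79e-06 and 1.02e-05).

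The last comparison tested whether the change from 12 hr to day 4 differed between the genotypes (n = 4, 4, 4 and 3). No single gene passed: limma called 0 genes, the smallest adjusted p was 0.0707, and 2177 genes had an unadjusted p below 0.05. The difference for psq was -0.36 ± 0.13 (SE, adjusted p = 0.204) and for Egfr -0.2 ± 0.15 (adjusted p = 0.507). Drs had -3.7 ± 0.99 (adjusted p = 0.138).

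In the test of the difference, 10 gene lists shifted, but 3 with the length and level trend removed, 5 with E_EHT replicate 1 kept, 16 without dim genes and 17 without EP_EHT replicate 4. Oxidative phosphorylation genes had a mean difference of 0.27, a more positive change with psqRNAi, with 0 of 31 past the test over all genes and 6 up adjusted over the list alone (camera adjusted p = 5.44e-09). Ribosome biogenesis and Myc genes had 0.26, with 0 of 17 over all genes and 11 up adjusted over the list alone (camera adjusted p = 8.88e-08). Cell cycle and DNA replication genes had 0.16, with 0 of 32 over all genes and 6 up adjusted over the list alone (camera adjusted p = 0.000312). Ribosomal protein genes had 0.13 with 0 of 23 either way (camera adjusted p = 0.000115), and 0.01 with the length and level trend removed (camera adjusted p = 0.983). The lists whose change was lower with psqRNAi were antimicrobial immunity (mean -0.54, camera adjusted p = 0.00681, 0 of 19, 1 down adjusted over the list alone), ecdysone response (-0.47, 0.00683, 0 of 20) and neurons and glia (-0.33, 0.0158, 0 of 12). They also included wing disc patterning (-0.18, 0.00539, 0 of 34), Hippo targets (-0.17, 0.0328, 0 of 9, 1 down adjusted over the list alone) and cell polarity and junctions (-0.14, 0.00325, 0 of 24). The 4 without such a count had 0 adjusted over the list alone, and all 10 lists had an adjusted p of 0.68 to 0.689 with an estimated correlation.

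Without EP_EHT replicate 4 this test called 345 genes, 311 up and 34 down, and with array weights it called 139. Without any other single array it called 0. The shifts of Hippo targets, ecdysone response, wing disc patterning, antimicrobial immunity and neurons were each lost without at least 1 of the 15 arrays, and that of cell polarity with E_EHT replicate 1 kept. Without E_EHT replicate 2 antimicrobial immunity had -0.26 (camera adjusted p = 0.223). Without EP_EHT replicate 2 ecdysone response had -0.25, Hippo targets -0.1, cell polarity -0.08 and wing disc patterning -0.06, and the last had -0.29 without EP_EHT replicate 4. The other 21 lists had camera adjusted p from 0.0518 to 0.945.

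**Figure D3:**
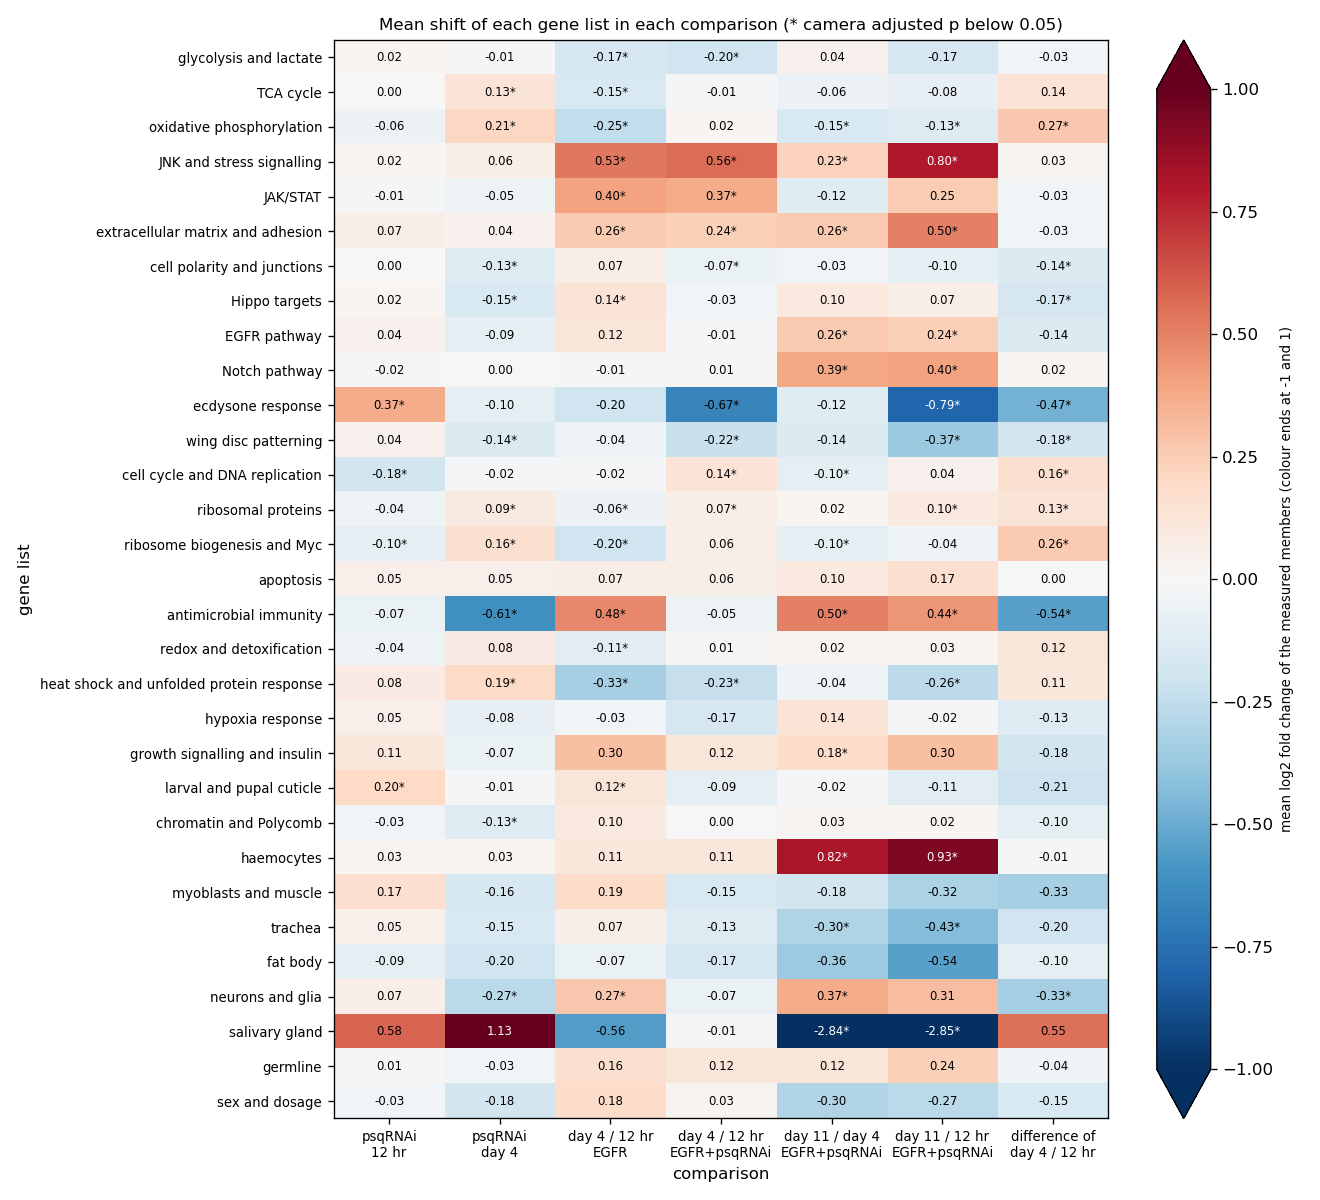
Mean log2 fold change of the measured members of each gene list (vertical axis) in each of the 7 comparisons (horizontal axis), with an asterisk where the camera adjusted p with a preset correlation lay below 0.05 and colours that end at -1 and 1. Oxidative phosphorylation genes show -0.25 from 12 hr to day 4 with EGFR and 0.21 between the genotypes at day 4, and haemocyte markers show 0.93 from 12 hr to day 11.

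On an axis through the 25 genes that changed at least 2-fold at 12 hr, with 0 at the mean of E_Ctrl and 1 at that of EP_Ctrl, the EP_EHT arrays lay at 0.81 to 0.9, the EP_LNT arrays at 0.82 to 0.9 and all 4 E_EHT arrays, the one left out included, at -0.03 to 0.05. Of the lists called at 12 hr, at day 4 cell cycle had -0.02, ecdysone response -0.1, cuticle -0.01 (camera adjusted p = 0.468, 0.358 and 0.796) and ribosome biogenesis 0.16, in the other direction.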

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

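The levels of the transcripts lncRNA:roX1 and lncRNA:roX2 were tested after they were seen, and the correction for gene length and level and the simulation of shared arrays were also chosen after the data were seen.

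For the change from 12 hr to day 4, 10 lists passed the test of the difference between genotypes with a preset correlation, against 3 with the length and level trend removed and 17 without EP_EHT replicate 4. The change was more positive with psqRNAi for oxidative phosphorylation (camera adjusted p = 5.44e-09), ribosome biogenesis and Myc (8.88e-08), ribosomal proteins (0.000115) and cell cycle and DNA replication (0.000312). It was 0.00325 for cell polarity and junctions, 0.00539 for wing disc patterning, 0.00681 for antimicrobial immunity, 0.00683 for the ecdysone response, 0.0158 for neurons and glia and 0.0328 for Hippo targets, all lower with psqRNAi. With an estimated correlation all had an adjusted p between 0.68 and 0.689.

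Of 278 gene and group values tested for 1 array far from the other 3, 20 passed Dixon's 95% critical value (7.2%), where chance gives about 1 in 20. On EP_LNT replicate 4, 9 genes stood apart: chinmo (gap over range 0.913), egr (0.913), moody (0.841), NimC1 (0.937), Pvf1 (0.833), SPARC (0.886) and Sr-CI (0.862) were low, and hh (0.865) and kni (0.8294) high. On EP_EHT replicate 2, Ilp8 (0.953) and nclb (0.872) were high and Spn100A (0.961) low, and on EP_EHT replicate 4 Sgs8 was low, at 8.6 against 12.66 to 12.99 (0.924). Among the arrays of 12 hr, snoRNA:Psi18S-640g was high (0.923) and SPH93 low (0.923) on E_Ctrl replicate 1, snoRNA:Psi18S-525b was high on E_Ctrl replicate 2 (0.871) and BomT2 low on E_Ctrl replicate 4 (0.937). ftz-f1 was low on EP_Ctrl replicate 2 (0.846), and BomS6 (0.913) and sty (0.878) were high on EP_Ctrl replicate 3. On the array that was left out, E_EHT replicate 1, 352 genes lay more than 4-fold above each of the other 3 arrays of its group and 0 below, against at most 65 above and 23 below on any other array.

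The first pattern weighed is the set of 94 genes called in the same direction in both comparisons of psqRNAi, Mrp4 and the snoRNA cluster among them. A single outlying array is argued against, since at least 64 genes were called the same way in both without any 1 of the 15 arrays, and the comparisons share no array. Genetic background linked to the RNAi transgene cannot be told apart from an effect of psqRNAi. Of 91 located genes, 38 pairs lay within 200 kb (10000 random sets: median 15, 95th percentile 22). Clusters of related genes also give close pairs. Arm 2L held 30.8% of these 91 and 18.9% of all located genes, and X 5.5% and 15.5%. The random 95th percentile of 31.9%, for whichever arm held most, does not test 2L. An effect of psqRNAi itself stays open as the biological explanation that the design names, and the psq value at 12 hr, which did not pass, does not check the knockdown.

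The second pattern is that the oxidative phosphorylation and ribosome biogenesis lists shifted down by day 4 with EGFR and up with psqRNAi against EGFR alone at day 4. Both comparisons use the same 3 E_EHT arrays with opposite sign. In 10000 simulations of unchanged groups the 2 lists were opposed in 70.3% and 69.6%, so the opposition is no evidence. Shifts as large came in 0%, but this cannot test lists picked for them. A trend with gene length and level as the whole cause is argued against: with it removed, 66.1% of the mean shift between the genotypes at day 4 was left for oxidative phosphorylation (0.21 before and 0.14 after, adjusted p = 5.56e-05) and 80.1% for ribosome biogenesis (adjusted p = 0.000626), so the trend may account for part. A single outlying array of day 4 is argued against too, since the highest camera adjusted p of both lists without any 1 of the 7 arrays was 0.00021, on the preset correlation, against 0.677 at day 4 with an estimated correlation. Low values shared by all E_EHT arrays and a difference between the genotypes both stay open, the first untested: without those arrays, day 4 against 12 hr with psqRNAi had mean shifts of 0.02 and 0.06.

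The third pattern is the distance of EP_LNT replicate 4 from the other 3 arrays of day 11. On an axis over 1510 genes, 0 was the mean of EP_EHT and 1 that of the other EP_LNT arrays. Replicate 4 lay at 0.31, between EP_EHT (0 to 0.12) and the others (0.91 to 0.96). Only those arrays chose the genes, so a mislabelled day 4 sample stays open. Discs from fewer males may be part of the difference, since lncRNA:roX1 stood 4.18 below the lowest of the other 18 arrays, whose range was 0.66, and lncRNA:roX2 stood 3.14 below, with a range of 1.25. A tumor at an earlier stage was not tested.

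Other splits of the same arrays into groups of the same sizes tested whether chance could give as many genes, which was taken as argued against where under 5% of splits did. This was so at 12 hr, where 1 of 35 splits, the real one, gave 325 genes (highest other 1). It was also so for day 4 against 12 hr with EGFR (882, 1 of 35, highest other 43) and with psqRNAi (633, 1 of 35, highest other 1) and for day 11 against 12 hr (2963, 1 of 35, highest other 108). The difference between genotypes had 0 genes past adjustment and 2177 with an unadjusted p below 0.05 (2 of 100, highest other 2374). Its splits also broke up the genotype effect, so chance stays open. Chance cannot be excluded between the genotypes at day 4 (425, 2 of 35), where the split that put EP_EHT replicate 4 with the EGFR arrays gave 1264 genes. Nor can it be between day 11 and day 4 (937, 2 of 35), where exchanging EP_EHT replicate 2 and EP_LNT replicate 4 gave 1633. Such counts point to a structure among the arrays other than the groups. For the number of lists shifted it cannot be excluded in any comparison: as many lists came from 24 of 35 splits at 12 hr (real 4, highest other 15), 14 at day 4 (11 and 17), and 2 for day 4 against 12 hr with EGFR (14 and 15). The other numbers were 19 with psqRNAi (10 and 16), 10 for day 11 against day 4 (13 and 18), 3 for day 11 against 12 hr (13 and 14) and 44 of 100 for the difference between genotypes (10 and 20).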

How the results depend on the processing

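The correction for gene length and level was the only alternative chosen after seeing the data; for every value that moved, the cause was not tested unless said. Counts of changed genes stayed within 1.5 times of the reported count except as follows. With E_EHT replicate 1 kept, 206 genes changed at 12 hr (325 reported), 605 between day 4 and day 11 (937) and 1 in the difference between genotypes (0). A further quantile normalization gave 1 there, and removing dim genes gave 1 there and 645 between the genotypes at day 4 (425), with 7123 genes tested. Array weights gave 873 at 12 hr, 804 between the genotypes at day 4, 2238 for day 4 against 12 hr with EGFR (882), 1773 between day 4 and day 11 and 139 for the difference between genotypes. With only the groups compared in the model these were 64 between the genotypes at day 4, 267 for day 4 against 12 hr with psqRNAi (633), 252 between day 4 and day 11 and 2 for the difference between genotypes. All 4 hold EP_EHT, whose pairs spread most (SD up to 0.497), while day 4 against 12 hr with EGFR, on no more arrays, rose to 1177. Leaving out 1 array in turn gave 153 to 512 at 12 hr, 179 to 1134 between the genotypes at day 4, and 273 to 965 and 307 to 833 for day 4 against 12 hr with EGFR and with psqRNAi. It gave 539 to 1510 between day 4 and day 11, 2350 to 3363 between 12 hr and day 11 and 0 to 345 for the difference between genotypes. With an estimated correlation, 1 of the 75 gene list shifts was called. Over the 7 comparisons, other alternatives called 56 to 78 shifts in all and left-out arrays 69 to 88. Of the 178 calls of named genes, 137 to 178 were made under the alternatives fixed beforehand and 151 to 176 without 1 array. Directions turned for a few values: Egfr between the genotypes at day 4 with E_EHT replicate 1 kept (0.02), Egfr for day 4 against 12 hr with psqRNAi (-0.02 to 0.18 without 1 array) and for day 11 against day 4 (0 to 0.19). With the length and level trend removed, those that turned were Egfr at 12 hr (0), at day 4 (0.05) and in the difference between genotypes (0.05), psq for day 4 against 12 hr with psqRNAi (0.01), and ribosomal proteins between the genotypes at day 4 (0), for day 4 against 12 hr with EGFR (0.05, adjusted p = 0.0168) and in the difference between genotypes (0.01). The 3 ribosomal protein shifts had been called, as 0.09, -0.06 and 0.13. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated from -0.4 to 0.37, so no pairing was used. With a replicate block the 7 counts were 323, 357, 621, 645, 978, 3049 and 0, with 71 list shifts in all and 173 calls of named genes. Of 2210 gene values under other settings, 2093 kept their direction and side of the threshold, 94 lost the call, 18 gained one and 5 turned; without 1 array these were 1385, 222, 4 and 2 of 1613. Of 746 list values under other settings, 680 kept both, 63 lost the call and 3 turned, and without 1 array 580 of 645 kept both and 65 lost it. No background probe values were used here, so signal over background limits dim genes to an unknown degree.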

Other observations

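The gene sets of this part were put together after the data were seen, while the test of neighbouring genes was set before its result was seen. Of 23 piRNA pathway genes, 8 rose, 3 fell and 12 did not pass by day 11 with EGFR and psqRNAi (n = 4 and 4). Of all genes 22.1% changed, and enrichment was not tested. krimp rose 7.17-fold (log2 fold change 2.84 ± 0.11 SE, limma adjusted p = 1.58e-10), and SoYb 3.26-fold (1.7 ± 0.1, adjusted p = 1.37e-08). The gene del rose 2.57-fold (1.36 ± 0.08, adjusted p = 9.08e-09) and AGO3 2.34-fold, and piwi, vret, zuc and BoYb rose by 1.38-fold to 1.57-fold. armi, mael and tapas fell (-0.36, -0.23 and -0.36), and the call of mael was lost without at least 1 of the 8 arrays (highest adjusted p = 0.0679). krimp, AGO3, del and SoYb were also the 4 that rose by day 4 with EGFR alone. The homeotic genes Dfd and Scr, which act in head and anterior thoracic segments, rose by day 11, by log2 fold changes of 1.42 ± 0.13 and 1.5 ± 0.17 (adjusted p = 9.27e-07 and 1.02e-05).

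The myoblast regulators twi, htl, Him and zfh1 rose by day 11, 2.04, 2.51, 1.96 and 1.86-fold (adjusted p = 8.67e-07, 6.95e-06, 3.94e-05 and 0.00147). The muscle genes Mlc1, TpnC73F, up, Tm2 and Mlp84B fell 7.3, 6.96, 3.78, 3.1 and 2.19-fold (adjusted p = 0.00231, 0.0027, 0.0128, 0.01 and 0.00119). Without EP_Ctrl replicate 4, where the myoblast and muscle list stood high (8.97), these falls were 4.86, 4.59, 2.35, 2.05 and 1.86-fold (highest adjusted p = 0.0219). That list had 5 rises and 5 falls, so the choice of genes made the contrast.

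It was tested whether genes that rose by day 11 lay next to one another, as chromosome domains regulated together might produce. Of 1597 risen genes with a position, 297 consecutive pairs both rose, against a median of 196, a 95th percentile of 217 and a highest value of 243 in 10000 random sets. Pairs that both fell were also frequent, 194 among 1322 genes against a median of 134 and a highest value of 175. Tandem copies of related genes, which give neighbours that respond alike, were not tested apart.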
